A study of Mus musculus with 24 samples.

How the data were processed

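Single cells of mouse cerebellum were profiled at 12 ages (E10 to E17, P0, P4, P7 and P10), with 2 libraries per age and 24 in all, per the labels. The labels give papain dissociation, capture of polyA RNA in droplets with the first version of a 10x Genomics kit, and replicates called biological. The authors deposited 1 matrix per library that holds the UMI count of each gene in each barcode, made with Cell Ranger 1.1.0 on genome build mm10, per the submitters' processing notes. The annotation release and aligner settings are not given in the sources used here. The deposited count values are whole numbers that sum to a different total in each library, and each matrix lists 27998 genes and every barcode of the kit, so that cells had not been selected. The 56 gene symbols that occur more than once were kept apart by identifier. Gene locations are those of GENCODE M21, built on the same assembly.

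A barcode was called a cell if it held at least 1000 UMIs (or 0.1 of the 99th percentile of the 3000 largest barcodes of its library, if that was higher), at least 500 genes, and at most 10% of its UMIs from mitochondrially encoded genes. Of 65365 barcodes over the UMI limit, 615 fell below the gene minimum and 7 over the mitochondrial limit. Of the 64743 called cells, 1621 (2.50%) with the highest Scrublet scores of their library were removed as likely doublets, at 0.8% per 1000 cells, and 63122 were kept. Called cells held a median of 3837 UMIs and 1760 genes. By age the median of kept cells ran from 1925 UMIs at E14 to 11294 at E10. Library totals ran from 1983446 to 24303757 UMIs. E12 replicate 1 had 15 kept cells and 1.93% of its UMIs in cells, E12 replicate 2 had 630 cells and 71.6%, and the other libraries had between 80.5% and 94.2%.

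Cells were normalised to 10000 UMIs, and 2000 variable genes, 50 principal components and 15 neighbours gave 57 clusters with Leiden at resolution 1.5 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). The 52 clusters of at least 20 cells were compared with 22 lists of cell type markers. A marker counted where at least 10% of the cluster's cells held a UMI of it and it was at least 1.5-fold above the other clusters, with 20 CPM added to both sides. A list was eligible with at least 3 such markers and a positive mean fold, and Pax2, Ptf1a and Eomes had to be among them for the 3 classes named for or by these genes. The cluster took the eligible list with most members among its 10 most specific genes, and of equal ones that with the higher mean fold. It stayed unnamed where no list was eligible, or where another list had more members among those genes. The lists were written before the data were examined, and this naming rule was set afterwards. It named 47 clusters in 19 classes, and 5 stayed unnamed. With the cells in clusters under 20 cells, 6003 cells (9.51%) had no name. Class names end in "-like", since they rest on these markers alone.

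UMI counts were summed over the kept cells of a library, or over its cells of 1 class where it held at least 20. Genes were filtered with filterByExpr and scaled by TMM, and ages were compared in edgeR 4.0.16 with a robust quasi-likelihood fit, 1 coefficient per age and Benjamini-Hochberg adjusted p-values at 0.05 (R 4.3.3, limma 3.58.1). Every library entered the whole-sample fit of 15000 genes with 12 residual degrees of freedom, so that all ages give the spread. The fits by class used 19 libraries and 9 residual degrees of freedom for neural progenitor-like, 12 and 5 for Purkinje-like, 16 and 8 for granule progenitor-like, 14 and 7 for granule neuron-like and 14 and 7 for astroglia-like cells. The 3 age comparisons, their classes, the tests and the named genes rule were written before the data were examined. Cell numbers per class were tested in edgeR with the library's number of cells as its size. The difference in change between granule neuron-like and granule progenitor-like cells was tested as an interaction, with the library as a block. Classes and comparisons outside this plan were not tested.

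Gene lists, 24 in all and written before the data were examined, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, in 177 tests of lists with at least 3 measured members. Of these 90 were called with the preset and 21 with the estimated correlation. Named genes are, per comparison, the 5 with the largest log2 fold change in each direction among those past the threshold with at least 50 CPM at the higher age and both libraries of one age above both of the other. Unnamed gene models, globins, mitochondrially encoded, X-inactivation and Y-linked genes were left out, as was a clone name met afterwards. Added to these are the 2 members with the smallest p of each list set against the comparison, and 23 panel genes for the time course. Other genes are named where they are the exceptions to a count, and Etv5, Gbx2, Fgf8 and En1 at P10 were chosen after their values were seen. A fold against an age with 0 counts is a lower bound, computed against 3 counts over the libraries of that age. With 1 to 3 counts the ratio of summed counts is given with an exact 95% counting interval (Clopper-Pearson, scipy 1.17.1). These intervals cover counting error alone. The upper limit of a share of 0 is that of 3 cells, and it too covers counting error alone. For shares of cells with a UMI each cell was thinned to 1500 UMIs.

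Each test was tried on simulated data before it was run on the measured counts, apart from a first trial of the model fit that was stopped before it wrote a result. In the simulated counts of E14 against E10, edgeR recovered 16 of 100 genes changed 2-fold and 81 of 100 changed 4-fold, and called 5 unchanged genes. In the Purkinje-like comparison it recovered 8 and 59 of 100, and in the interaction 0 and 43 of 100. These counts were simulated with a dispersion of 0.05. The common dispersion fitted afterwards was 0.0244 in the whole sample and 0.0190 in Purkinje-like cells, so that recovery in the measured data may differ. The test of shares recovered 4 of 4 changed classes in each age comparison and called 1 unchanged class in that of E14 against E10. Only more frequent classes were changed there, by 4-fold, so that this trial does not cover classes that go to 0.

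The alternatives were DESeq2 1.42.0 in place of edgeR, no filter on low counts, library totals without TMM, glmTreat against a 1.5-fold change, at least 2000 UMIs per cell, no doublet removal, a mitochondrial limit of 5%, neural cells alone, Leiden at resolution 3 (80 clusters), at least 50 cells per library, TMM on cell numbers, thinning to 1000 UMIs, the replicate number as a block, and leaving out each library in turn. Where a library is left out, the lone library of its age is assumed to vary like those of the other ages. Over 55 pairs of ages, residuals of libraries with the same replicate number had a median correlation of 0.0141, and 4 pairs were over 0.1, so that the libraries were not treated as paired. The labels give no batch or date. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.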

Results

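RNA counts of single cells from mouse cerebellum were compared at 12 ages, from embryonic day 10 (E10) to postnatal day 10 (P10), with 2 libraries per age. After filtering 63122 cells remained, between 645 at E12 and 8152 at P4. A library held between 1983446 and 24303757 UMIs (unique molecular identifiers, 1 per captured RNA molecule). Gene levels are given in CPM, the UMI counts of a gene in the summed cells of a library scaled to a common library total, after TMM scaling, as the mean ± SD of the libraries of an age (n = 2 throughout). Changes between ages are log2 fold changes ± SE from edgeR's quasi-likelihood model. In the summed cells of all classes, a change can come from the share of a class or from levels within it. The whole-sample tests do not tell these apart. The labels call the libraries of an age biological replicates and do not name animals or litters, so that a p-value measures the spread between these libraries. In 162 of 162 named results of an age comparison, both libraries of one age lay above both of the other, which was a condition for naming genes by the size of their change and so is no measure of replicate spread. E12 replicate 1 held 15 kept cells, with 1.93% of its UMIs in them, and E12 is not an age of any compared pair. The E12 libraries do enter the estimate of spread in the whole-sample tests and the tests of class shares.

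Neural progenitor-like cells, named by genes of the dividing cells that line the ventricle, made up 58.7 ± 3.24% of cells at E10, 28.2 ± 2.33% at E14, 4.37 ± 0.274% at P0 and 0.0882 ± 0.125% at P10. Roof plate-like cells, which carry genes of the dorsal midline, held 15.8 ± 0.0622% at E10, and at E14 they were 0 of 4551 cells, which allows a share of up to 0.0659%. Glutamatergic nuclear neuron-like cells, the excitatory output neurons of the cerebellum, were most frequent at E13, with 18.5 ± 0.854%. Purkinje-like cells, the inhibitory output neurons of the cortex, held 32.0 ± 1.70% at E14, 20.6 ± 4.72% at E15 and 0.972 ± 0.101% at P0. At E13 they held 0.418 ± 0.482%, while unnamed clusters held 21.9 ± 3.65%, 11.8 ± 1.105% and 5.28 ± 0.988% of cells. Among the specific genes of these clusters were Gad2, Foxp2, Lhx5 and Pnoc, so that the size of the rise to E14 may depend on the naming rule. At P7 Purkinje-like cells were 0 of 5543 cells, where counting error alone allows a share of up to 0.0541%. Shares are those of captured cells, and losses of a cell type in dissociation or capture were not measured. GABAergic progenitor-like cells, which share Ptf1a with the progenitors of inhibitory neurons, held 8.01 ± 0.160% at E13. Pax2 interneuron-like cells, the immature inhibitory interneurons, held 9.44 ± 0.384% at E15. Unipolar brush-like cells, excitatory interneurons marked by Eomes, held 11.2 ± 0.543% at P0. Astroglia-like cells, glia with genes of astrocytes and Bergmann glia, held 12.1 ± 0.0798% at P0 and 1.60 ± 0.230% at P10. Granule progenitor-like cells, the Atoh1-expressing dividing precursors of granule cells, held 8.49 ± 0.842% at E14 and 50.4 ± 2.25% at P4. Granule neuron-like cells, the small excitatory neurons of the cortex, held 0.0504 ± 0.0713% at E14, 17.4 ± 1.15% at P0 and 53.7 ± 0.158% at P10.

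**Figure D1:**
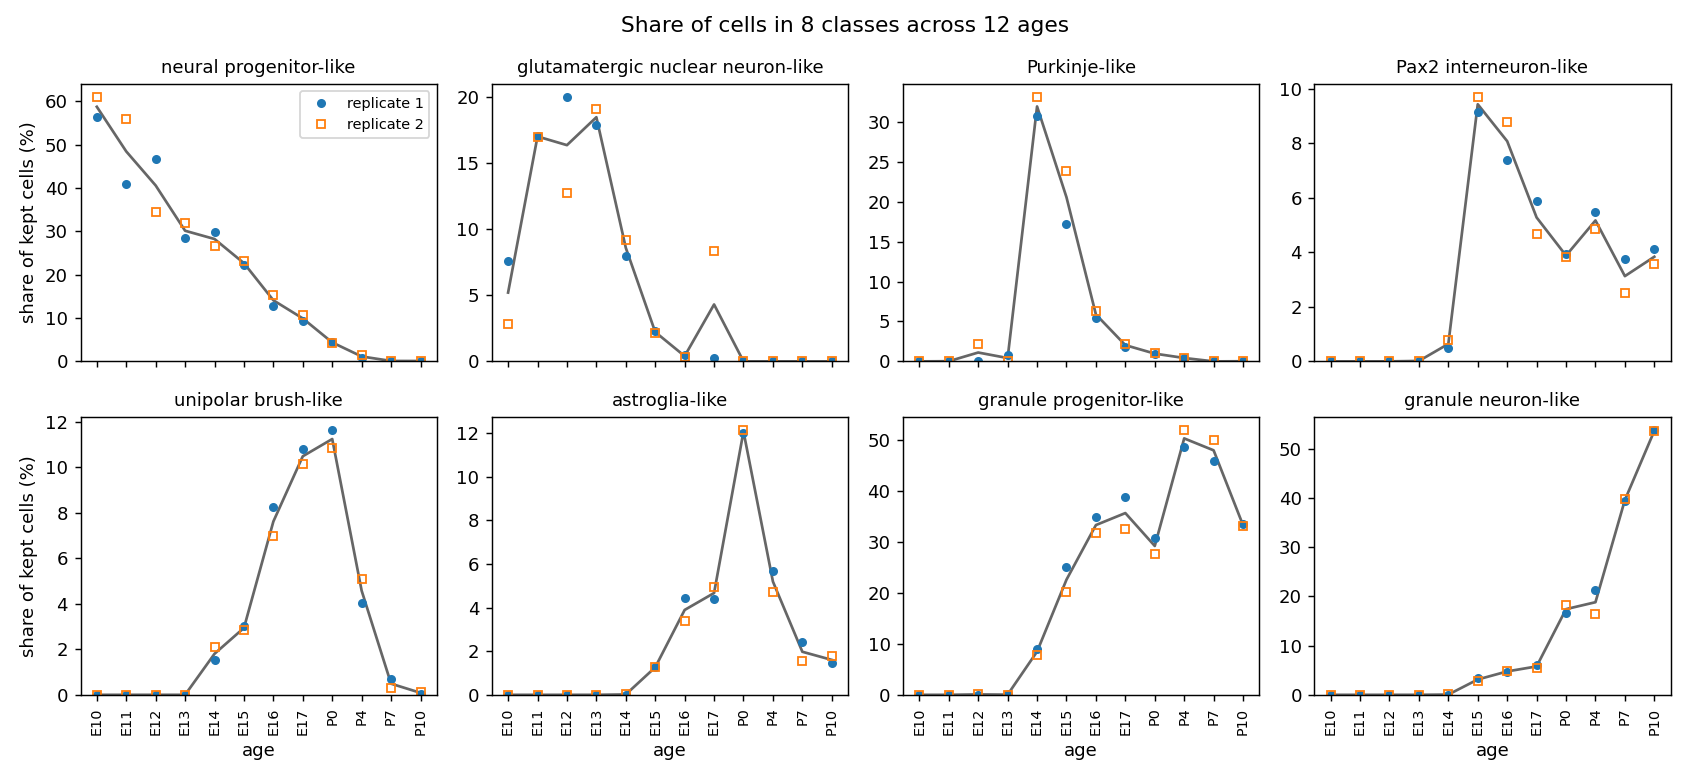
Share of cells (percent) in 8 cell classes at each of the 12 ages; points are the libraries of an age and lines join their means. Neural progenitor-like cells fall from 58.7% at E10 to 0.0882% at P10, Purkinje-like cells stand at 32.0% at E14, and granule neuron-like cells reach 53.7% at P10.

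Neurod1, a transcription factor of differentiating granule neurons (ENSMUSG00000034701, chromosome 2 from 79452521 to 79456751, minus strand, mm10), rose from 7.69 ± 1.79 CPM at E10 to 1411 ± 60.8 CPM at P10. Nfib, a transcription factor of late progenitors and glia (ENSMUSG00000008575, chromosome 4 from 82290173 to 82705750, minus strand), rose from 6.04 ± 1.03 to 1192 ± 40.1 CPM over the same span. At P10 neural progenitor-like and astroglia-like cells held 0.0882 ± 0.125% and 1.60 ± 0.230% of cells. Which classes carry the P10 level of Nfib was not tested. Foxp2, a transcription factor of Purkinje cells and nuclear neurons, was highest at E14 with 180 ± 48.4 CPM and stood at 8.02 ± 0.121 CPM at P10. Lhx9 of glutamatergic nuclear neurons stood at 211 ± 41.0 CPM at E13, with 182 and 240 CPM in its libraries. At E12 the library of 15 cells had 39.7 CPM of Lhx9 and the other 186 CPM, so that its highest age is left open. Ptf1a of GABAergic progenitors stood at 81.4 ± 6.73 CPM at E13 and at 67.9 ± 96.0 CPM at E12, where the library of 15 cells had 0 and the other 136 CPM, so that its highest age is left open. Pax2 of inhibitory interneurons was highest at E16 with 27.9 ± 0.620 CPM, and Eomes of unipolar brush cells at P0 with 56.5 ± 12.4 CPM. Calb1, a calcium-binding protein of Purkinje cells, stood at 55.8 ± 10.1 CPM at P4 and 1.40 ± 0.292 CPM at P7. Sox2 of progenitors fell from 83.7 ± 11.5 CPM at E11 to 10.1 ± 5.04 CPM at P10. Mki67, a marker of dividing cells, stood at 59.6 ± 0.641 CPM at E10, 13.1 ± 1.78 CPM at E13 and 138 ± 4.46 CPM at P10. Lin28b, an RNA-binding regulator of developmental timing, fell from 21.6 ± 7.27 CPM at E10 to 0.0436 ± 0.0616 CPM at P10. Over all 15000 genes tested, 12986 changed with age (edgeR's quasi-likelihood F test, Benjamini-Hochberg adjusted), and 13128 had an unadjusted p under 0.05. Of the 23 panel genes 21 changed with age, with an edgeR adjusted p of 1.67e-13 for Neurod1, 4.28e-15 for Nfib and 1.43e-11 for Foxp2. Foxj1 of ciliated cells had an edgeR adjusted p of 0.0598, and Gabra6 of mature granule neurons had too few counts to be tested.

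In cells thinned to 1500 UMIs each, the share with at least 1 Neurod1 UMI was 46.4 ± 3.96% at P0 and 82.2 ± 1.30% at P10, against a background in endothelial-like cells, which should lack the gene, of 5.63% (4 of 71 cells) at P0 and 32.6% (28 of 86 cells) at P10. Pooled over all ages this background was 6.67%, and the backgrounds of the other genes below are pooled in the same way unless an age is given. The median depth before thinning was 3799 UMIs in all kept cells and 4874.5 UMIs in all kept endothelial-like cells, of which 705 had at least 1500 UMIs. Without thinning the Neurod1 shares were 59.7% and 92.6%. Sox2 was seen in 9.89 ± 0.839% of thinned cells at E10 and 1.18 ± 0.384% at P10, against a background of 0.284%, and in 43.2% and 2.18% without thinning. For Foxp2 the thinned share was 19.2 ± 4.70% at E14 (23.7% without thinning), and its background was 5.71% (2 of 35 cells) at E14. The 1.35 ± 0.0505% at P10 lay below the pooled background of 1.56% and near the 1.16% (1 of 86 cells) of P10, so that it is not told apart from background. Atoh1 was seen in 20.4 ± 1.76% of thinned cells at E11, Lhx9 in 14.6 ± 1.92% at E13 and Eomes in 6.61 ± 0.766% at P0. Their backgrounds were 1.56%, 0.284% and 0.426%, and their shares without thinning 30.4%, 21.2% and 11.5%. These shares leave out 3266 cells with fewer than 1500 UMIs, of which 893 were at E14 and 0 at E10.

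**Figure D2:**
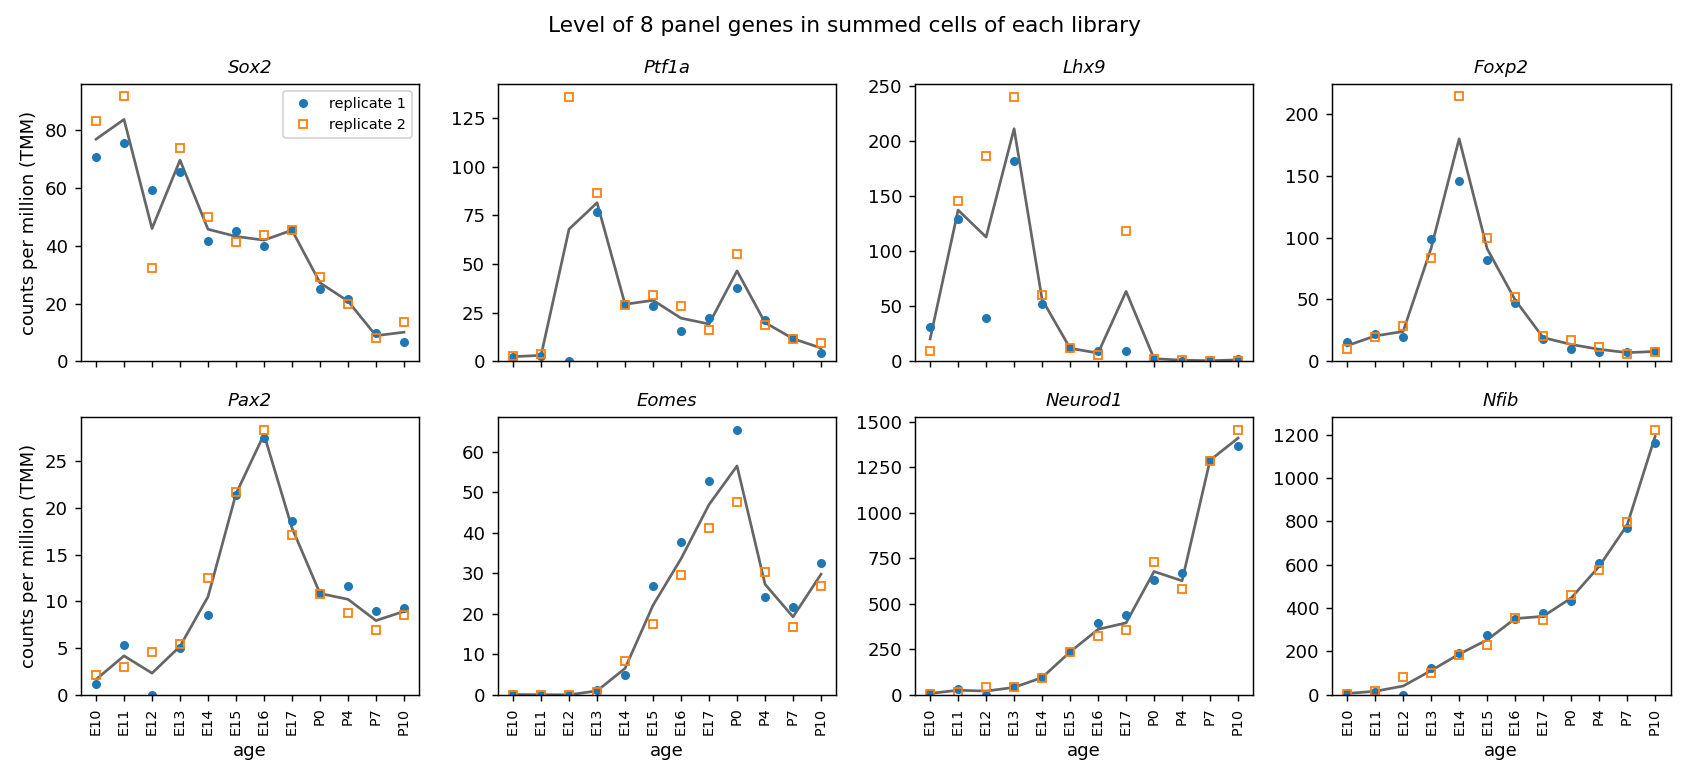
Level in CPM (TMM-scaled, linear axis from 0) of 8 genes in the summed cells of each library, by age; points are the libraries of an age and lines join their means. Foxp2 stands at 180 CPM at E14, Lhx9 at 211 CPM at E13 and Eomes at 56.5 CPM at P0, while Neurod1 and Nfib end at 1411 and 1192 CPM at P10.

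Between E10 and E14 Pcp4, a calmodulin-binding protein of Purkinje cells (chromosome 16 from 96467606 to 96525793, plus strand), rose to 217 ± 6.73 CPM at E14. Gad2, which makes GABA, and Slc32a1, which loads GABA into vesicles, rose to 121 ± 7.40 and 72.8 ± 16.5 CPM. Neurod2 and Neurod6, transcription factors of differentiating neurons, rose to 79.0 ± 10.8 and 91.7 ± 13.9 CPM. Nfib and Nfia, which act in late progenitors and glia, rose by log2 4.96 ± 0.223 and 4.20 ± 0.204. Skor1, a corepressor of Purkinje cells, and Nrxn3, a presynaptic adhesion protein, rose 177-fold and 203-fold. Igf2bp1, an RNA-binding protein of early progenitors (chromosome 11 from 95957163 to 96005940, minus strand), fell by 2.60 ± 0.205 on the log2 scale. Uhrf1, which keeps DNA methylation at replication, fell by 2.11 ± 0.129 and Id1, an inhibitor of differentiation downstream of BMP signals, fell by 2.45 on the log2 scale. Prtg of the early neural tube fell by 6.54 ± 0.439 and Colec12, a scavenger receptor of mesenchyme, fell by 6.70 ± 0.358 on the log2 scale. Pf4 of macrophages and Wfikkn1, a binding protein of growth factors, had 0 counts at E14, at least 438-fold and at least 167-fold lower than at E10. The hindbrain genes Hoxb2 and Hoxa2, 2 members of a list of 15 that could be tested, also had 0 counts at E14, each at least 25.2-fold lower than at E10.

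In the whole-sample test 7780 of 15000 genes changed from E10 to E14, 4021 up and 3759 down (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted; 8606 at an unadjusted p under 0.05). With library totals in place of TMM factors, 5046 were up and 2816 down, 64.2% up against 51.7%, and the median log2 change of all genes was 0.18 against -0.014. In edgeR the adjusted p was 2.62e-09 for Pcp4, 1.14e-12 for Nfib and 1.22e-11 for Colec12. It was higher for Krt18 of epithelia, at 0.00973 with a log2 change of -7.18 ± 2.02, and this call was lost without E14 replicate 1 (-7.32) or E14 replicate 2 (-6.99). For the genes near 0 at E10 the ratio has a wide 95% counting interval, 2473 (845 to 12003) for Pcp4 with 3 counts, 2085 (576 to 17233) for Gad2 with 2, 2766 (495 to 109399) for Neurod2 with 1 and 1610 (445 to 13317) for Neurod6 with 2.

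Of 40 cell cycle genes 39 fell from E10 to E14 (39 adjusted over the list alone), with an adjusted p of 5.21e-19 in limma's camera and adjusted p = 0.0932 with an estimated correlation. Of 12 heterochronic RNA-binding and chromatin genes, which set the timing of progenitor states, 10 fell (10 adjusted over the list alone, camera adjusted p = 6.32e-08; adjusted p = 0.0932 with an estimated correlation). Genes of synaptic vesicles and release rose in 20 of 21 cases (20 adjusted over the list alone, camera adjusted p = 7.51e-09; adjusted p = 0.18 with an estimated correlation). Purkinje and GABAergic genes rose in 17 and fell in 2 of 22 cases (19 adjusted over the list alone, camera adjusted p = 7.37e-10; adjusted p = 0.0943 with an estimated correlation). Gliogenic factors rose in 11 and fell in 1 of 13 cases, the fall being that of Fgfr3 (12 adjusted over the list alone, camera adjusted p = 8.46e-05; adjusted p = 0.18 with an estimated correlation). SHH pathway genes, which relay the mitogen from Purkinje cells, fell in 11 and rose in 1 of 15 cases (12 adjusted over the list alone, camera adjusted p = 0.000629; adjusted p = 0.18 with an estimated correlation). Axon growth and guidance genes rose in 19 of 24 cases (19 adjusted over the list alone, camera adjusted p = 1.03e-10; adjusted p = 0.0932 with an estimated correlation). Notch and progenitor genes fell in 10 and rose in 4 of 21 cases (15 adjusted over the list alone), and camera did not call the list (adjusted p = 0.115). The rhombic lip and glutamatergic nuclear neuron genes rose in 4 and fell in 4 of 15 cases (8 adjusted over the list alone, camera adjusted p = 0.342). Within it Reln, a secreted guidance protein, rose to 17.8 CPM and Slc17a6, a vesicular glutamate transporter, to 20.4 CPM. Beside these groups 8 of 12 mesenchymal genes and 15 of 19 early genes induced by tissue dissociation fell, and 7 of 10 mitochondrially encoded genes rose and 1 fell (8, 15 and 8 adjusted over the list alone). Their camera adjusted p values were 1.33e-05, 0.000158 and 0.0202, and adjusted p = 0.0932, adjusted p = 0.18 and adjusted p = 0.481 with an estimated correlation.

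Purkinje-like cells rose in share from E10 to E14 by log2 12.72 ± 1.18 and granule progenitor-like cells by 10.80 ± 0.778, in edgeR tests of cell numbers (adjusted p = 1.80e-07 and 1.17e-08). GABAergic progenitor-like, unipolar brush-like and Pax2 interneuron-like cells rose by 9.98 ± 1.05, 8.59 ± 1.01 and 7.13 ± 1.15. Roof plate-like cells fell by 11.70 ± 1.15 and mesenchymal-like cells by 8.20 ± 0.834 on the log2 scale (edgeR adjusted p = 4.57e-06 and 1.11e-06). In all 14 of 19 classes changed in share, 7 up and 7 down, and 8 changed when neural cells alone were counted, a test that leaves out the non-neural classes. Glutamatergic nuclear neuron-like cells did not pass the test, with log2 0.72 and an edgeR adjusted p of 0.442. At E10 100% of that class lay in 1 cluster, and at E14 75.2% and 24.1% lay in 2 others. Classes near 0 at one of the ages have fitted log2 values that depend on the prior count. The UMI limit for a cell was 2873.7 and 2821.4 in the E10 libraries and 1000 in those of E14. The alternative of at least 2000 UMIs lies below the E10 limits, so that shares at an equal limit were not compared. The fall in the share of neural progenitor-like cells was log2 -1.06 ± 0.394 (edgeR adjusted p = 0.0215). It was no longer past the threshold without E10 replicate 2 (-1.0), E14 replicate 1 (-1.14) or E14 replicate 2 (-0.98), and its sign turned when cell numbers were scaled by TMM (0.13). Endothelial-like and microglia-like cells passed with log2 -0.95 and -1.43, and the endothelial-like call was lost without E10 replicate 1 (-0.85) or E14 replicate 2 (-0.72). Its sign turned with TMM on cell numbers (0.24). The microglia-like call was lost without E10 replicate 1 (-1.12). The fall in brainstem or midbrain neuron-like cells, neurons with genes of neighbouring regions, was log2 -2.49 ± 0.668 (edgeR adjusted p = 0.00481). That call was lost without E14 replicate 2 (-2.24). Neural crest or cranial ganglion-like cells rose by log2 7.03, a call lost without the same library (6.56) and reversed in sign with Leiden at resolution 3 (-0.99). Mural-like cells of vessels rose by log2 7.93.

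Within neural progenitor-like cells Ndrg2, a cytoplasmic protein of astroglia, rose between E10 and E14 to 199 ± 7.10 CPM, 186-fold, and Aldh1l1, an enzyme of astrocytes, to 91.5 ± 7.23 CPM, 216-fold. Nfib rose to 284 ± 22.3 CPM and Slc1a3, a glutamate transporter of radial glia, to 316 ± 8.34 CPM. Dhrs3, an enzyme of retinoid metabolism, rose to 50.9 CPM. Crabp1 and Crabp2, which bind retinoic acid in the cell, fell to 10.3 ± 11.96 and 16.3 CPM from 749 ± 288 and 933 ± 16.02 CPM. Igdcc3 of the early neural tube fell to 8.61 CPM from 172 CPM, and Rrm2, which makes DNA precursors, fell to 441 ± 19.3 CPM from 1236 ± 158 CPM. Etv5 and Etv4, which answer FGF signals, rose 3.96-fold and by log2 1.12. For Ndrg2 the adjusted p in edgeR was 3.87e-16, for Nfib 6.11e-18, for Crabp2 1.97e-12 and for Etv4 0.00318. Wfikkn1 had 0 counts at E14 in this class, at least 59.5-fold lower than at E10. Pcp4 had 1 count at E10 and Lmcd1 3, and their ratios were 1055 (187 to 41930) and 568 (192 to 2770). Pcp4 is among the Purkinje markers, and Purkinje-like cells held 32.0 ± 1.70% of cells at E14. Whether its counts in this class came from other cells was not tested. In all 4064 of 12373 genes changed, 2000 up and 2064 down (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted; 5201 at an unadjusted p under 0.05). With library totals in place of TMM factors 3162 were up and 1026 down, 75.5% up against 49.2%, with a median log2 change of 0.25. Without E14 replicate 2 the number of changed genes was 2575. At E10 96.8% of the class lay in 1 cluster, and at E14 64.4% and 25.4% lay in 2 others.

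Gliogenic factors rose in 10 and fell in 1 of 13 cases in neural progenitor-like cells (12 adjusted over the list alone, camera adjusted p = 6.79e-13; adjusted p = 0.00136 with an estimated correlation). Heterochronic genes fell in 10 of 12 cases (10 adjusted over the list alone, camera adjusted p = 2.59e-08; adjusted p = 0.0038 with an estimated correlation), among them Igf2bp1, which fell by 2.46 on the log2 scale. Cell cycle genes fell in 32 of 40 cases (36 adjusted over the list alone, camera adjusted p = 3.04e-10; adjusted p = 0.0506 with an estimated correlation). The mid-hindbrain organizer genes, which pattern the boundary of midbrain and hindbrain, rose in 3 and fell in 1 of 18 cases (4 adjusted over the list alone, camera adjusted p = 0.936). Markers of other cell types moved in the same cells. Astroglial maturation genes rose in 14 and fell in 1 of 19 cases, granule lineage genes rose in 13 of 18 and synaptic genes in 10 of 19 (16, 13 and 10 adjusted over the list alone). Their camera adjusted p values were 2.77e-10, 3.99e-09 and 9.59e-06, and adjusted p = 0.00136, adjusted p = 0.0137 and adjusted p = 0.0038 with an estimated correlation. Mesenchymal genes fell in 4 of 7 cases (4 adjusted over the list alone, camera adjusted p = 0.0028; adjusted p = 0.0506 with an estimated correlation), and early genes induced by dissociation fell in 6 and rose in 1 of 19 (7 adjusted over the list alone, camera adjusted p = 0.00802; adjusted p = 0.441 with an estimated correlation).

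Between E14 and P0 Ccnd1, a cyclin of granule progenitors, rose to 197 ± 16.6 CPM from 26.9 CPM, and Ptch1, the receptor of SHH, rose to 28.8 CPM from 6.64 CPM. Neurod1 rose to 678 ± 69.9 CPM from 94.7 ± 6.21 CPM and Pax6, a transcription factor of granule cells and their progenitors, to 510.4 ± 48.5 CPM from 110.2 CPM. Nfix of late progenitors and glia rose to 181 ± 11.1 CPM from 22.6 CPM, and Olig1, of oligodendrocytes and other glia, rose 9.81-fold. Tbata, a microtubule-associated protein, rose to 53.4 ± 6.07 CPM, Cxcl12, a chemokine, to 72.5 ± 6.87 CPM and the neuropeptide gene Cartpt (chromosome 13 from 99898489 to 99901091, minus strand) to 172 ± 22.1 CPM. Foxp2 fell to 13.7 ± 5.13 CPM from 180 ± 48.4 CPM, and Robo3, a receptor of commissural axons, fell by 6.38 on the log2 scale. Over this span Purkinje-like cells went from 32.0 ± 1.70% to 0.972 ± 0.101% of cells. Nrgn, a calmodulin-binding protein of neurons, fell to 1.15 CPM from 158.7 ± 0.732 CPM, and Meis2, a transcription factor of neurons, fell to 1.84 CPM from 92.7 ± 16.5 CPM. Hmga2, a chromatin protein of early progenitors, fell by 2.86 ± 0.218 and Olig3 of the rhombic lip fell by 4.51 on the log2 scale. Fgf17, a growth factor of the midbrain-hindbrain boundary, had 0 counts at P0, at least 435-fold lower than at E14. Pcp2, a protein of Purkinje cells, rose to 41.0 ± 13.7 CPM from 3 counts at E14, a ratio of 147 (50.03 to 712).

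In the whole-sample test 4685 of 15000 genes changed from E14 to P0, 2322 up and 2363 down (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted; 6163 at an unadjusted p under 0.05). That number was 2688 without E14 replicate 2 and 3022 without P0 replicate 1. The edgeR adjusted p was 1.43e-10 for Ccnd1, 9.11e-08 for Neurod1, 1.07e-08 for Foxp2 and 1.14e-06 for Tbata. Astroglial maturation genes rose in 18 of 20 cases (19 adjusted over the list alone, camera adjusted p = 6.9e-15; adjusted p = 0.000273 with an estimated correlation). SHH pathway genes rose in 12 and fell in 1 of 15 cases (13 adjusted over the list alone, camera adjusted p = 3.82e-07; adjusted p = 0.141 with an estimated correlation). Cell cycle genes rose in 22 of 40 cases (26 adjusted over the list alone, camera adjusted p = 3.82e-07; adjusted p = 0.248 with an estimated correlation). Granule lineage genes rose in 12 and fell in 3 of 20 cases (15 adjusted over the list alone, camera adjusted p = 0.00549; adjusted p = 0.52 with an estimated correlation). Purkinje and GABAergic genes fell in 13 and rose in 4 of 22 cases (18 adjusted over the list alone, camera adjusted p = 0.0132; adjusted p = 0.52 with an estimated correlation). Rhombic lip and glutamatergic nuclear neuron genes fell in 9 and rose in 4 of 15 cases (13 adjusted over the list alone, camera adjusted p = 0.00188; adjusted p = 0.395 with an estimated correlation). Gliogenic factors rose in 9 of 13 cases (9 adjusted over the list alone, camera adjusted p = 0.00549; adjusted p = 0.426 with an estimated correlation). Heterochronic genes fell in 3 and rose in 2 of 12 (5 adjusted over the list alone, camera adjusted p = 0.0312; adjusted p = 0.483 with an estimated correlation). The synaptic vesicle list was not called (7 up and 3 down of 21; 11 adjusted over the list alone, camera adjusted p = 0.448), and its median of log2 -0.19 differed in sign from its mean of 0.26 and from the test. Beside these groups early genes induced by dissociation rose in 12 of 19 cases (12 adjusted over the list alone, camera adjusted p = 8.22e-07; adjusted p = 0.187 with an estimated correlation). Oligodendrocyte and myelin genes rose in 8 of 15 cases (8 adjusted over the list alone, camera adjusted p = 0.00071; adjusted p = 0.248 with an estimated correlation).

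Astroglia-like and granule neuron-like cells rose in share from E14 to P0 by log2 8.83 ± 0.560 and 7.98 ± 0.504 (edgeR adjusted p = 7.75e-09 for both). Oligodendrocyte lineage-like cells, the cells that form myelin and their precursors, rose by 5.92 ± 0.684, unipolar brush-like cells by 2.62 ± 0.351 and Pax2 interneuron-like cells by 2.55 ± 0.365. Granule progenitor-like cells rose by 1.79 ± 0.303 (edgeR adjusted p = 7.26e-05), a call lost with TMM on cell numbers (0.30). An unnamed cluster with Atoh1, Barhl1 and Mycn among its specific genes held 0.613 ± 0.391% of cells at E14 and 8.40 ± 0.253% at P0. It is not counted in the class, so that the size of this rise may depend on the naming rule. Purkinje-like cells fell by 5.04 ± 0.587 on the log2 scale (edgeR adjusted p = 2.36e-06) and neural progenitor-like cells by 2.69 ± 0.420. Glutamatergic nuclear neuron-like cells were 0 of 6138 cells at P0, which allows a share of up to 0.0489%, against 8.59 ± 0.824% at E14 (edgeR adjusted p = 0.000144). In all 8 classes rose and 5 fell. The rise in microglia-like cells of log2 1.08 was lost without E14 replicate 1 (0.80) or P0 replicate 1 (0.86), and its sign turned when cell numbers were scaled by TMM (-0.40). Ciliated-like cells, with genes of motile cilia, rose by log2 6.39, and brainstem or midbrain neuron-like and neural crest-like cells fell by 7.82 and 4.87 on the log2 scale.

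Within Purkinje-like cells Car8, which binds the IP3 receptor of Purkinje cells (chromosome 4 from 8143362 to 8239041, minus strand), rose between E14 and P0 to 2036 ± 238 CPM from 1 count, a ratio of 6608 (1182 to 261335). Pcp2 (chromosome 8 from 3623371 to 3625545, minus strand) rose to 2523 ± 1290 CPM from 2 counts, a ratio of 4195 (1158 to 34691). Itpr1, the IP3 receptor itself, rose to 182 ± 22.8 CPM from 1 count, a ratio of 583 (101 to 23354). Thy1, a surface protein of mature neurons, had 0 counts at E14 and 194 ± 46.9 CPM at P0, at least 217-fold higher. Syt1, the calcium sensor of vesicle release, rose to 222 ± 24.02 CPM from 35.4 CPM, and Gria1, a subunit of glutamate receptors, rose 4.40-fold. Tubb3, a tubulin of young neurons, fell by 1.23 ± 0.105 on the log2 scale, and Robo2, an axon guidance receptor, rose to 159.9 ± 36.4 CPM from 45.2 CPM. Robo3 and Crabp2 had 0 counts at P0, at least 37.7-fold and at least 34.5-fold lower than at E14. The edgeR adjusted p was 2.79e-14 for Car8 and 0.000496 for Pcp2. Car8, Pcp2 and Itpr1 are among the markers by which clusters were named Purkinje-like. At E14 95.04% of the class lay in 1 cluster and at P0 98.3% in another. The class held 484 and 987 cells in the E14 libraries and 32 and 27 in those of P0. Il22 and Iltifb, near-identical cytokine gene copies on chromosome 10, had 0 counts at E14 and were at least 189-fold and at least 82.8-fold higher at P0. Reads that match both copies leave uncertain which of them was measured.

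In all 1894 of 7759 genes changed in Purkinje-like cells, 1074 up and 820 down (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted; 2781 at an unadjusted p under 0.05). DESeq2 called 1333, 982 up and 351 down, 73.7% up against 56.7%. Without P0 replicate 1 the number of changed genes was 1104, and without P0 replicate 2 it was 1181. Synaptic vesicle genes rose in 10 of 16 cases (10 adjusted over the list alone, camera adjusted p = 4.65e-05; adjusted p = 0.207 with an estimated correlation). Voltage-gated channel genes rose in 6 of 16 cases (7 adjusted over the list alone, camera adjusted p = 0.00856; adjusted p = 0.219 with an estimated correlation). Postsynaptic receptor genes rose in 6 and fell in 1 of 14 cases (8 adjusted over the list alone, camera adjusted p = 0.0761). Axon growth and guidance genes rose in 6 and fell in 6 of 21 cases (12 adjusted over the list alone, camera adjusted p = 0.878), with a median of log2 -0.01 and a mean of -0.05 while the test pointed up. Beside these, granule lineage genes fell in 6 of 18 cases, rhombic lip genes in 4 of 7, and endothelial genes rose in 3 and fell in 1 of 5 (7, 4 and 4 adjusted over the list alone). Their camera adjusted p values were 0.0255, 0.00801 and 0.0681, and adjusted p = 0.238, adjusted p = 0.207 and adjusted p = 0.227 with an estimated correlation.

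Between P0 and P10 Mbp, a protein of myelin, rose to 206 ± 77.1 CPM from 15.8 CPM in the summed cells. Cntn2, an adhesion protein of young granule cell axons, rose to 184 ± 17.3 CPM from 20.4 CPM, and Sfrp1, a secreted WNT antagonist, to 356 ± 15.8 CPM from 53.8 CPM. Grin2b, a subunit of the NMDA receptor, rose 4.07-fold and Rbfox3, a splicing factor of mature neurons, rose 2.65-fold. Mki67 rose 3.95-fold. Aqp4, a water channel of astroglia (chromosome 18 from 15389496 to 15410982, minus strand), rose to 86.6 ± 13.8 CPM from 31.5 CPM, while Slc1a3, a glutamate transporter of the same cells, fell to 148.5 ± 14.5 CPM from 360.4 ± 20.2 CPM. Both are levels in the summed cells of all classes. Astroglia-like cells held 12.1 ± 0.0798% of these at P0 and 1.60 ± 0.230% at P10, so that the fall of Slc1a3 need not lie within that class. Cartpt fell to 1.45 CPM from 172 ± 22.1 CPM and Calb1 fell to 2.11 CPM from 44.4 CPM. Pcp2 fell by 5.16 on the log2 scale. Calb1 and Pcp2 are genes of Purkinje cells. Purkinje-like cells held 0.972 ± 0.101% of cells at P0 and 0.0147 ± 0.0208% at P10. Whether these genes changed within that class over this span was not tested. Hes5, a target of Notch, fell to 10.4 CPM from 113 ± 24.3 CPM, and Epha5, an ephrin receptor, fell to 3.50 CPM from 59.6 CPM. Etv5, Gbx2, Fgf8 and En1, genes of the midbrain-hindbrain boundary, fell by 2.53, 4.82, 4.64 and 1.40 on the log2 scale.

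In the whole-sample test 4919 of 15000 genes changed from P0 to P10, 2510 up and 2409 down (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted; 6440 at an unadjusted p under 0.05). With library totals in place of TMM factors 3387 were up and 1728 down, 66.2% up against 51.0%, with a median log2 change of 0.13. The number of changed genes was 2993 without P0 replicate 1, 3252 without P0 replicate 2 and 3193 without P10 replicate 2. Cartpt and Mki67 had adjusted p-values of 2.17e-06 and 0.00132 in edgeR. Notch and progenitor genes fell in 15 and rose in 1 of 21 cases, the rise being that of Notch2 (18 adjusted over the list alone, camera adjusted p = 3.28e-11; adjusted p = 0.137 with an estimated correlation). Mid-hindbrain organizer genes fell in 10 of 18 cases (11 adjusted over the list alone, camera adjusted p = 5.09e-06; adjusted p = 0.0436 with an estimated correlation). Oligodendrocyte and myelin genes rose in 10 and fell in 1 of 15 cases (11 adjusted over the list alone, camera adjusted p = 1.05e-08; adjusted p = 0.0533 with an estimated correlation). Synaptic vesicle genes rose in 14 and fell in 1 of 21 cases (16 adjusted over the list alone, camera adjusted p = 0.00272; adjusted p = 0.723 with an estimated correlation). Purkinje and GABAergic genes fell in 7 and rose in 2 of 22 cases (9 adjusted over the list alone, camera adjusted p = 0.00228; adjusted p = 0.687 with an estimated correlation). Cell cycle genes rose in 12 and fell in 3 of 40 cases (16 adjusted over the list alone) and were not called as a group (camera adjusted p = 0.0667). Postsynaptic receptor genes rose in 7 and fell in 6 of 21 (13 adjusted over the list alone, camera adjusted p = 0.455), and axon growth and guidance genes rose in 7 and fell in 6 of 24 (14 adjusted over the list alone, camera adjusted p = 0.52), with a median of log2 0.11, a mean of -0.085 and a test that pointed up. SHH pathway genes fell in 6 and rose in 2 of 15 (9 adjusted over the list alone, camera adjusted p = 0.226), granule lineage genes rose in 7 and fell in 5 of 20 (12 adjusted over the list alone, camera adjusted p = 0.225) and astroglial maturation genes fell in 8 and rose in 3 of 20 (12 adjusted over the list alone, camera adjusted p = 0.311). Beside these, mesenchymal genes rose in 6 and fell in 1 of 12 cases (8 adjusted over the list alone, camera adjusted p = 0.0524).

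Granule neuron-like cells rose in share from P0 to P10 by log2 1.62 ± 0.307 (edgeR adjusted p = 0.000573). Unipolar brush-like cells fell by 6.95 ± 0.478 and neural progenitor-like cells by 5.58 ± 0.591 on the log2 scale (edgeR adjusted p = 4.14e-08 and 3.53e-07). Eomes, required for the unipolar brush-like name, stood at 56.5 ± 12.4 CPM at P0 and 29.8 ± 3.97 CPM at P10 in the summed cells. The share of the class thus fell far more than its marker, and the cause was not tested. Purkinje-like cells fell by 5.67 ± 1.01 and astroglia-like cells by 2.91 ± 0.325 on the log2 scale (edgeR adjusted p = 0.000253 and 4.23e-06). Granule progenitor-like cells did not pass the test, with log2 0.19 and an edgeR adjusted p of 0.716. An unnamed cluster with Atoh1, Barhl1 and Mycn among its specific genes held 8.40 ± 0.253% of cells at P0 and 0 of 6942 at P10. It is not counted in the class, so that the sign of this change may depend on the naming rule. The fall in GABAergic progenitor-like cells was log2 -1.50 (edgeR adjusted p = 0.00517). It was no longer past the threshold without P0 replicate 2 (-1.26) or P10 replicate 1 (-1.33). Mural-like cells, the pericytes and muscle cells of vessels, fell by 1.28 on the log2 scale (edgeR adjusted p = 0.0211). That call was lost without P0 replicate 1 (-1.22), P0 replicate 2 (-1.34) or P10 replicate 2 (-0.93).

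Within granule progenitor-like cells Cntn2 rose between P0 and P10 to 106 ± 12.7 CPM from 9.74 CPM and Sfrp1 to 620.5 ± 24.1 CPM from 113 CPM. Otx1, a transcription factor of the caudal cerebellum, rose 27.4-fold, and Zbtb20, a repressor of neurons and glia, rose to 431 CPM from 87.6 CPM. Ccnd2, a cyclin of granule progenitors, rose to 1562 CPM from 735 CPM while Ccnd1 fell to 141 CPM from 402 CPM. Hes1, a target of Notch, fell by 4.63 ± 0.249 and Igfbp2, which binds insulin-like growth factors, fell by 6.91 ± 0.373 on the log2 scale. Fscn1, which bundles actin, fell to 17.5 CPM from 237 CPM, and Igf2bp1 had 0 counts at P10, at least 80.5-fold lower than at P0. The edgeR adjusted p was 5.66e-07 for Igfbp2 and 9.54e-12 for Hes1. In all 3890 of 12224 genes changed, 2008 up and 1882 down (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted; 5136 at an unadjusted p under 0.05). With library totals in place of TMM factors 3066 were up and 1104 down, 73.5% up against 51.6%, with a median log2 change of 0.18. Leaving out P0 replicate 1 gave 2300 changed genes. Cntn2 and Sfrp1 are among the markers by which granule classes were named. The class drew 33.2% and 22.7% of its P0 cells from 2 clusters that held 47.3% and 38.1% at P10, and 15.7%, 6.25% and 5.91% of its P0 cells from 3 clusters that held none of its P10 cells.

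Notch and progenitor genes fell in 10 of 19 cases in granule progenitor-like cells (11 adjusted over the list alone, camera adjusted p = 0.000185; adjusted p = 0.0327 with an estimated correlation). Heterochronic genes fell in 5 and rose in 1 of 9 (6 adjusted over the list alone, camera adjusted p = 0.000443; adjusted p = 0.0327 with an estimated correlation). Voltage-gated channel genes rose in 9 of 15 (9 adjusted over the list alone, camera adjusted p = 0.000466; adjusted p = 0.0327 with an estimated correlation) and synaptic genes rose in 11 and fell in 2 of 20 (14 adjusted over the list alone, camera adjusted p = 0.000443; adjusted p = 0.0327 with an estimated correlation). SHH pathway genes fell in 5 and rose in 2 of 14 (8 adjusted over the list alone, camera adjusted p = 0.574), and cell cycle genes rose in 9 and fell in 3 of 40 (12 adjusted over the list alone, camera adjusted p = 0.254). Gliogenic factors rose in 5 and fell in 1 of 12 (6 adjusted over the list alone, camera adjusted p = 0.0394; adjusted p = 0.205 with an estimated correlation). Markers of other cell types moved too. Microglial genes rose in 9 of 9 cases (9 adjusted over the list alone, camera adjusted p = 9.58e-06; adjusted p = 0.0327 with an estimated correlation), endothelial genes in 5 of 7 (5 adjusted over the list alone, camera adjusted p = 0.0879), and myelin genes rose in 5 and fell in 1 of 10 (6 adjusted over the list alone, camera adjusted p = 0.0394; adjusted p = 0.289 with an estimated correlation), among them Mbp, which reached 60.6 CPM from 11.4 CPM. Early genes induced by dissociation fell in 8 and rose in 1 of 19 (12 adjusted over the list alone, camera adjusted p = 0.0016; adjusted p = 0.0742 with an estimated correlation). In barcodes of at most 100 UMIs, which hold mostly free RNA, the 9 microglial genes had a median log2 ratio of 1.86 between P10 and P0, against 2.83 in the class.

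Within granule neuron-like cells Slc17a6, a vesicular glutamate transporter, rose between P0 and P10 to 58.7 CPM from 7.20 CPM, and Syn2, a protein of synaptic vesicles, rose 3.70-fold. Grin2b and Gria4, subunits of glutamate receptors, rose 4.84-fold and 4.66-fold. The calcium channel genes Cacna2d1 and Cacna1a rose to 233 and 44.8 CPM from 81.0 and 13.3 CPM. Itsn1, a scaffold of endocytosis, rose to 249 ± 32.5 CPM from 22.1 CPM, and Tgfb2, a secreted growth factor, to 123 ± 18.3 CPM from 9.48 CPM. Mgll, which breaks down an endocannabinoid, rose 13.6-fold. Galr1, a galanin receptor, rose to 58.5 ± 12.2 CPM from 1 count, a ratio of 273 (48.8 to 10816). Cartpt fell by 8.05 ± 0.584 on the log2 scale and Epha5 fell to 4.84 CPM from 138 CPM. For Cartpt the adjusted p was 3.93e-05 in edgeR. In all 3290 of 10699 genes changed, 1709 up and 1581 down (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted; 4366 at an unadjusted p under 0.05). With library totals in place of TMM factors 2489 were up and 931 down, 72.8% up against 51.9%, with a median log2 change of 0.20. Leaving out P0 replicate 1 gave 1886 changed genes. At P0 51.4% and 35.9% of the class lay in 2 clusters, and at P10 80.3% and 19.3% lay in 2 others. Voltage-gated channel genes rose in 10 and fell in 2 of 15 cases (13 adjusted over the list alone, camera adjusted p = 0.00556; adjusted p = 0.0802 with an estimated correlation). Synaptic genes rose in 11 and fell in 3 of 21 (15 adjusted over the list alone, camera adjusted p = 0.018; adjusted p = 0.155 with an estimated correlation). Postsynaptic receptor genes rose in 5 and fell in 4 of 14 (10 adjusted over the list alone, camera adjusted p = 0.934), with a median of log2 0.40, a mean of -0.13 and a test that pointed down. Axon growth and guidance genes fell in 7 and rose in 4 of 23 (13 adjusted over the list alone, camera adjusted p = 0.667), with a median of log2 0.08, a mean of -0.23 and a test that pointed down. Beside these, microglial genes rose in 4 of 6 cases, globins in 3 of 4, and cell cycle genes rose in 17 and fell in 4 of 40 (4, 3 and 23 adjusted over the list alone). Their camera adjusted p values were 0.00665, 0.0123 and 0.018, and adjusted p = 0.115, adjusted p = 0.176 and adjusted p = 0.176 with an estimated correlation.

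Within astroglia-like cells Aqp4 rose between P0 and P10 to 4173 ± 417 CPM from 234 ± 2.40 CPM and S100b, a calcium-binding protein of astrocytes, to 954 ± 78.3 CPM from 88.3 ± 19.0 CPM. Ptprz1, a receptor phosphatase of glia, rose 3.78-fold and Zbtb20 3.43-fold. Msmo1 and Pmvk, enzymes of cholesterol synthesis, rose 2.60-fold and 2.55-fold. Fam107a of astrocytes and Slc22a4, a carnitine transporter, had 0 counts at P0 and were at least 129-fold and at least 124-fold higher at P10. Mcm6, a part of the replicative helicase, fell to 14.1 CPM from 174 CPM and Pcna, the replication clamp, to 71.5 CPM from 384 CPM. Sfrp2, a secreted WNT modulator, had 0 counts at P10, at least 30.6-fold lower than at P0. Olig1 fell to 5.54 CPM, with 2 counts, from 202.2 ± 31.6 CPM, a ratio of 36.7 (10.1 to 304). For Aqp4 the adjusted p was 9.00e-16 in edgeR. Aqp4 and S100b are among the markers by which the class was named, and 85.6% of its P0 cells and 98.2% of its P10 cells lay in the same cluster. The class held 427 and 314 cells in the P0 libraries and 51 and 60 in those of P10. In all 1520 of 6406 genes changed, 905 up and 615 down (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted; 2196 at an unadjusted p under 0.05). Leaving out P10 replicate 2 gave 974 changed genes. With library totals in place of TMM factors the median log2 change was 0.13.

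Astroglial maturation genes rose in 15 and fell in 1 of 19 cases in astroglia-like cells (16 adjusted over the list alone, camera adjusted p = 6.5e-10; adjusted p = 0.00552 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 17 (14 adjusted over the list alone, camera adjusted p = 2.17e-05; adjusted p = 0.0483 with an estimated correlation). Gliogenic factors rose in 9 and fell in 2 of 12, the falls being those of Olig1 and Sox8 (11 adjusted over the list alone, camera adjusted p = 0.000781; adjusted p = 0.0483 with an estimated correlation). Cell cycle genes fell in 16 of 30 (19 adjusted over the list alone, camera adjusted p = 1.68e-10; adjusted p = 0.0341 with an estimated correlation). Beside these, early genes induced by dissociation fell in 8 of 14 cases, synaptic genes rose in 5 of 9 and mesenchymal genes in 2 of 3 (9, 8 and 3 adjusted over the list alone). Their camera adjusted p values were 0.000288, 0.00431 and 0.0063, and adjusted p = 0.118, adjusted p = 0.0483 and adjusted p = 0.118 with an estimated correlation.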

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

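All 4 tests of an explanation in this part had their predictions written before the result was seen. The bounds of the E17 tests were set aside afterwards, for the reasons given there. The numbers of brainstem or midbrain neuron-like cells at E17 were also compared afterwards. The comparison of granule neuron-like with granule progenitor-like cells is given first, because the interaction test found genes whose change from P0 to P10 differed between them.

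The change from P0 to P10 differed between these classes for 824 of 11932 genes, 342 with a larger log2 change in neurons and 482 with a smaller one (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted; 2201 at an unadjusted p under 0.05). Without P0 replicate 1 this number was 399. Hes1, a target of Notch, had a difference of log2 2.99, since it went from 86.2 to 3.42 CPM in progenitors and from 6.13 to 1.87 CPM in neurons. Syt4, a vesicle protein of young neurons, had a difference of log2 -3.94 (edgeR adjusted p = 6.92e-10), going from 57.2 to 5.81 CPM in neurons while it stood at 3.31 and 5.10 CPM in progenitors. Tspan7, a membrane protein of neurons, and Camk2n1, an inhibitor of CaM kinase II, had differences of log2 -2.69 and -2.52, with falls in neurons from 162 to 23.6 and from 180 to 17.5 CPM. Car3, a carbonic anhydrase, had the largest difference of the named genes, log2 4.04 (edgeR adjusted p = 4.67e-13), going from 63.4 to 12.1 CPM in progenitors and from 4.98 to 16.5 CPM in neurons. The chemokines Cxcl14 and Cxcl12 had differences of log2 2.91 and -2.26, and Pgf, a growth factor of vessels, one of log2 -2.41. The mitotic genes Nek2 and Plk1 had differences of log2 3.35 and 3.17, and in neurons they stood at 5.69 and 8.64 CPM at P10, against 52.7 and 102 CPM in progenitors. At P0 they stood at 0.499 and 1.07 CPM in neurons, from 2 counts of Nek2 and 4 of Plk1, and for Nek2 the ratio of P10 over P0 in neurons was 13.3 (3.50 to 113). For Nek2 the adjusted p was 0.000555 in edgeR. Without P0 replicate 1 the differences of Nek2 (2.90) and Plk1 (2.11) were no longer past the threshold. The call of Pgf was lost without P10 replicate 2 (-2.0). With Leiden at resolution 3 the differences of Cxcl14 (0.25), Pgf (-0.52) and Nek2 (1.44) were no longer past the threshold.

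Microglial genes rose from P0 to P10 in granule progenitor-like cells, which should lack them, in 9 of 9 cases, with a median log2 change of 2.83. Doublets of a granule cell and a microglial cell are argued against as the whole cause, because 5 of 2313 cells with at least 5 UMIs of the list held 7.516% of its 785 UMIs, and 609 cells held any. Free RNA in the droplets may contribute, since the same genes had a median log2 ratio of 1.861 (1.55 to 2.82) in barcodes of at most 100 UMIs, above the 1.5 set beforehand. C1qa went from 39.9 to 161 CPM there and from 1.92 to 8.18 CPM in the class. Age itself stays open and was not tested apart from this.

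Glutamatergic nuclear neuron-like cells differed between the libraries of E17, with 0.25% (8 cells) in replicate 1 and 8.36% (180 cells) in replicate 2. A loss of shallow cells in replicate 1 stays open. With at least 2000 UMIs per cell the ratio of the shares was 31.5, against 33.4 over all kept cells, which met the bound written beforehand against it, but that bound was wrong because a stricter limit cannot bring back cells already lost in replicate 1. Tissue from beside the cerebellum in replicate 2 stays open as well. None of the 180 cells (0%) lay in a cluster that held under 5% of the E12 and E13 cells of the class, which met the bound written beforehand against this explanation, but that bound was wrong because 1 cluster held all 188 cells of the class from both libraries of E17 and 46.6% of those earlier cells, so that clusters do not separate the libraries, and because replicate 2 also held 13 brainstem or midbrain neuron-like cells against 1. No biological explanation was tested. E17 is not an age of any compared pair, but its libraries enter the estimate of spread behind the tests, also that of the share of this class.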

How the results depend on the processing

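All alternatives here were planned before the data were examined, apart from the tests without E12 replicate 1 for the whole-sample contrasts and class shares, which were chosen after the result was seen. For the 172 named fold changes 2347 alternative values kept direction and call, 13 kept the direction and lost the call, and 0 reversed. These genes were picked by large changes past the threshold or the smallest p of a list, which favours such stability. Alternatives in which a gene was not tested or had no adjusted p are not counted. Main counts stayed within 1.5 times in 172 cases and moved further in 22.

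With edgeR's glmTreat, which tests for a change above 1.5-fold, 4519 genes of the whole sample and 1787 of progenitors were called between E10 and E14. Between E14 and P0 it called 1746 of the whole sample and 964 in Purkinje-like cells. Between P0 and P10 it called 1540 of the whole sample, 1046 in granule progenitors, 1025 in granule neurons and 813 in astroglia. Leaving out 1 library gave 12722 to 13544 genes changed with age, 5808 to 8121 between E10 and E14, 2688 to 5024 between E14 and P0 and 2993 to 5331 between P0 and P10, where the highest value of each contrast is that without E12 replicate 1. By class it gave 2575 to 3115 in progenitors, 1104 to 1588 in Purkinje-like cells, 2300 to 2792 in granule progenitors, 1886 to 2339 in granule neurons, 974 to 1154 in astroglia and 399 to 790 in the interaction. The replicate block gave 12948 genes changed with age and 7784, 4635 and 4928 in the whole-sample contrasts, and changed no other call. Of the 177 camera tests, 90 were called with the preset and 21 with the estimated correlation. With neural cells alone, where non-neural classes are not counted, 8 classes changed in share between E10 and E14. Too few Purkinje-like libraries held at least 50 cells for a value.

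The share tests depended on the scaling. With TMM on cell numbers the sign turned between E10 and E14 for endothelial-like (0.24) and neural progenitor-like cells (0.13), between E14 and P0 for GABAergic progenitor-like (-1.02), endothelial-like (-1.37) and microglia-like cells (-0.40), and between P0 and P10 for endothelial-like cells (-0.019). With Leiden at resolution 3 it turned for neural crest-like cells between E10 and E14 (-0.99), and for Pax2 interneuron-like (0.21) and granule progenitor-like cells (-0.15) between P0 and P10. The Pax2 share of P10 against P0 also turned with at least 2000 UMIs (0.067) and without doublet removal (0.0034). Leaving out 1 library took it from -0.13 to 0.085, above 0 without P0 replicate 1 (0.0053) or P10 replicate 2. The endothelial-like share of P0 against E14 ran from -0.17 to 0.37, below 0 without P0 replicate 1 or E14 replicate 2 (-0.087). The erythroid-like share ran from -3.33 to 2.15, above 0 without E14 replicate 2. The endothelial-like share of P10 against P0 ran from -0.10 to 0.44, below 0 without P0 replicate 2. The cause was not tested. With Leiden at resolution 3 the interaction of Nek2 (1.44), Cxcl14 (0.25) and Pgf (-0.52) was no longer called. Depth limits genes of 3 counts or fewer, the Purkinje-like cells of P0 and E12 replicate 1.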

Other observations

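No test of an explanation was run in this part, and its values were chosen after the results were seen. Haemoglobin transcripts, which come from red blood cells, took 75334 ± 47104 CPM at E11, 1811 ± 301 CPM at E14, 32304 ± 17389 CPM at E16 and 498 ± 610 CPM at P0, summed over 7 genes (mean ± SD, n = 2). Erythroid-like cells were 4.72 ± 2.71% of cells at E11 and 1.54 ± 0.949% at E16. Cholesterol synthesis genes, summed over 19, were highest at E13 with 2484 ± 55.4 CPM, against 1193 ± 3.02 CPM at E10. Axon growth and guidance genes, summed over 24, were highest at the same age with 14086 ± 655 CPM. The list of Pax2 interneuron genes summed to 938 ± 62.3 CPM at E13 and 75.0 ± 15.3 CPM at P7, while Pax2 itself was highest at E16.

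Cell cycle genes, summed over 40, stood at 8056 ± 206 CPM at E10, 2757 ± 276 CPM at E14 and 6265 ± 907 CPM at P7. SHH pathway genes stood at 1607 ± 153, 502 ± 38.2 and 2234 ± 124 CPM at the same ages. Gliogenic factors stood at 97.9 ± 12.3 CPM at E10 and 2834 ± 165 CPM at P10. Mitochondrially encoded genes, which rise with stressed or damaged cells, stood at 14018 ± 356 CPM at E14 and 5307 ± 125 CPM at P10. Early genes induced by dissociation stood at 2943 ± 220 CPM at E10, 1429 ± 45.6 CPM at E14 and 3038 ± 137 CPM at P0.

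Of the 5 unnamed clusters, the largest held 2204 cells, among whose most specific genes were Sp5, Tlx3, Ntf3 and Otx2, beside the granule progenitor genes Atoh1, Barhl1 and Mycn. It made up 12.5 ± 1.79% of cells at E17, 8.40 ± 0.253% at P0 and 1.57 ± 0.576% at P4. The next held 1649 cells with Gad2, Robo3, Tfap2b and Foxp2, which inhibitory neurons express, and made up 21.9 ± 3.65% of cells at E13 and 1.69 ± 0.598% at E14. Another held 1304 cells with Cdkn1c, Tfap2b, Lhx5 and Nhlh2 and made up 11.8 ± 1.105% at E13 and 6.90 ± 0.411% at E14. A cluster of 523 cells with Otp, Pnoc and Tfap2b made up 5.28 ± 0.988% at E13. The last held 319 cells with Gng3, Gap43 and Cartpt. At E13 Purkinje-like cells were 0.418 ± 0.482% of cells.

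Ciliated-like cells were most frequent at P4, with 0.842 ± 0.151% of cells. Mesenchymal-like cells held 7.94 ± 4.10% at E10 and 1.01 ± 0.457% at P4. Gdf10, a gene of Bergmann glia, was highest at P0 with 123 ± 7.20 CPM, and Pdgfra of oligodendrocyte precursors at P7 with 75.3 ± 2.66 CPM.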
